A study of Mus musculus with 18 samples.

How the data were processed

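Gene expression was measured on Affymetrix arrays in the cardiac ventricles of 18 male mice, 1 heart per array. The labels give the strain as CR7BL6 and the age as 10 weeks. The 6 groups, taken from the sample titles, were 2 control and 4 SRFHKO hearts at day 8 after tamoxifen, and 3 hearts each of control, SRFHKO, control with phenylephrine (PE) and SRFHKO with PE at day 25. The titles call the replicates biological.

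For each of 45101 probe sets and each array, the deposited table gives an intensity on a linear scale. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised, and per the submitters' processing notes the intensity came from GCOS, the Affymetrix scanner software, whose version is not given in the sources used here. The signal algorithm, scaling target and any filter are not given in the sources used here either. The deposited intensity was not brought to a common level by the authors: 2% trimmed means lay between 46.6 and 148, so each array was scaled to the common trimmed mean of 90.6 before any test. A pseudocount of 2 was added, a value set from the median scaled value of 18.8, and log2 was taken. Fold changes are therefore on the log2(scaled signal + 2) scale, which understates changes of dim genes. Where a named gene past the threshold lay below the filter limit given below on any array of the dimmer group, its fold is given as a lower bound. This is the mean of the brighter group over that of the dimmer with such arrays raised to the limit, chosen after seeing the data. The bound allows for dim signal only and not for the spread between hearts, so the true fold can lie below it. The limit stands in for a background level, which was not used here.

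The 64 control probe sets were left out, as were probe sets whose mean over the 18 arrays lay below the 40th percentile (log2 value 3.58, a scaled signal of 9.96), leaving 27000. Gene names came from the platform annotation, updated through gene IDs with RefSeq names of assembly GRCm38.p6, used for names only. Of the probe sets on the array, 34945 had 1 gene symbol, 932 had several and 9160 had none; the gene ID was found for 34754 of those with 1 symbol and not for 204, which keep the annotated symbol. Of those passing the filter, 22880 had 1 symbol, 616 had several and 3504 had none. Each gene was read from its probe set with the highest mean, an _x_at probe set being taken only where there was no other, which gave 12610 genes. A single probe set per gene can miss transcripts that another probe set reads. The number of arrays limits the precision, and signal near the filter limit is the least precise.

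Tests were run in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). One linear model with a mean per group was fitted over the 18 arrays, so that the 2 control arrays of day 8 borrow the spread of all groups, with empirical Bayes moderation and an intensity trend. The 7 contrasts were SRFHKO against control at day 8, at day 25 without PE and at day 25 with PE, PE against no PE in each genotype, and the interactions of PE and of day with genotype. For Myh7 alone, 2 further contrasts were run after the result was seen: SRFHKO without PE against control with PE, and control at day 8 against control at day 25. P values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors of fold changes are standard errors and errors of group levels are SD. With 3 arrays against 3, an exact permutation of a single value cannot go below p = 0.1.

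Before the data were examined, 28 gene lists and 15 lists of cell type markers were fixed, of which 42 had at least 3 measured members; the thymus marker list had fewer and was not tested. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. Several lists share members, such as the cardiomyocyte markers and the sarcomere list. The genes named were also fixed by rule: per contrast the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap (5 each way for the interactions, without the overlap condition), 15 core genes, up to 4 members per list described, and the 5 with the smallest p where fewer than 5 passed.

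The steps were tested on simulated data in which 200 of 12610 genes were changed. For SRFHKO against control at day 25 without PE, 53.7% of genes changed by 1 on the log2 scale and 83.3% of those changed by 2 were recovered, with 9 false calls among 109. At day 8 the same shares were 53.7% and 84.8%, for PE in control hearts 65.7% and 83.3%, and for the interaction of PE and genotype 28.4% and 72.7%. Camera called 0 of 42 simulated lists without an effect and recovered a shift of 0.3 placed in the fatty acid oxidation list. The simulated genes were drawn independently of each other. This therefore does not show how often camera calls lists whose genes move together, as genes in real hearts can.

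Alternatives tried were no pseudocount and a pseudocount of 9.40, no filter and a filter at the 60th percentile, quantile normalisation, all probe sets or their mean per gene, a fit on the compared groups or days alone, no trend or a robust trend, array weights, the replicate number as a block, and leaving out each array in turn. The brightness of each array as a covariate was chosen after seeing the data. Named genes were followed under only part of these. That part was no pseudocount, a pseudocount of 9.40, quantile normalisation, the mean of probe sets, the compared groups alone, the block, brightness and single arrays left out. The filters, all probe sets, the compared days alone, the trend settings and array weights were not run for named genes. Probe sets with several symbols entered no test by gene, and those with none appear only as a count.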

Results

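Serum response factor (SRF) is a transcription factor of muscle and growth-response genes. The series asked how deletion of its gene in adult mice changes expression in the heart, at baseline and under PE, an agonist of alpha-1 adrenergic receptors. Mutant mice (SRFHKO) and their control littermates, which carry the SRF-flex2neo allele, had all been given tamoxifen at 0.7 mg on 3 days. Hearts were taken at day 8 (2 control, 4 SRFHKO) or at day 25 (3 in each of 4 groups), and PE was delivered by osmotic minipump at 80 mg/kg/day between day 10 and day 25. The trimmed mean intensity before scaling was 132 ± 9.19 (SD, n = 2) in control and 133 ± 16.2 (SD, n = 4) in SRFHKO arrays at day 8. At day 25 it was 57.3 ± 10.96 in control, 65.1 ± 11.6 in control with PE, 75.6 ± 6.89 in SRFHKO and 79.9 ± 4.94 in SRFHKO with PE (SD, n = 3 each). SRFHKO arrays of day 25 were thus brighter than control arrays, 1.33-fold without and 1.24-fold with PE (exact permutation test stratified by PE, two-sided p = 0.005, the smallest that its 400 regroupings can give). Day and array run cannot be told apart, since no hybridisation date was used here, and the 7 main contrasts compare days only through the difference between genotypes. Correlations between arrays lay between 0.924 and 0.973, and 0 pairs of arrays held identical values.

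Srf itself was read by 2 probe sets. The brighter one had log2 levels of 7.72 ± 0.39 (SD, n = 2) in control and 7.95 ± 0.23 (SD, n = 4) in SRFHKO hearts at day 8, and 7.48 ± 0.15 and 7.42 ± 0.24 (SD, n = 3 each) at day 25. The SRFHKO minus control differences in log2 were 0.23 ± 0.20 and 0.27 ± 0.20 for the 2 probe sets at day 8, -0.06 ± 0.19 and -0.54 ± 0.19 at day 25 without PE, and -0.19 ± 0.19 and 0.02 ± 0.19 with PE. The smallest limma adjusted p among these was 0.138, for the dimmer probe set at day 25 without PE. With single arrays of the compared groups left out, the differences of the brighter and the dimmer probe set ran from -0.04 to 0.51 and from 0.06 to 0.47 at day 8, their ends set by the 2 control arrays. They ran from -0.16 to 0.07 and from -0.71 to -0.29 at day 25 without PE, with both upper ends without SRFHKO replicate 2, and from -0.40 to -0.06 and from -0.10 to 0.10 with PE; the smallest adjusted p was then 0.0632. Where these probe sets lie relative to the deleted part of Srf is unknown here, so they check nothing about the genotype labels.

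**Figure D1:**
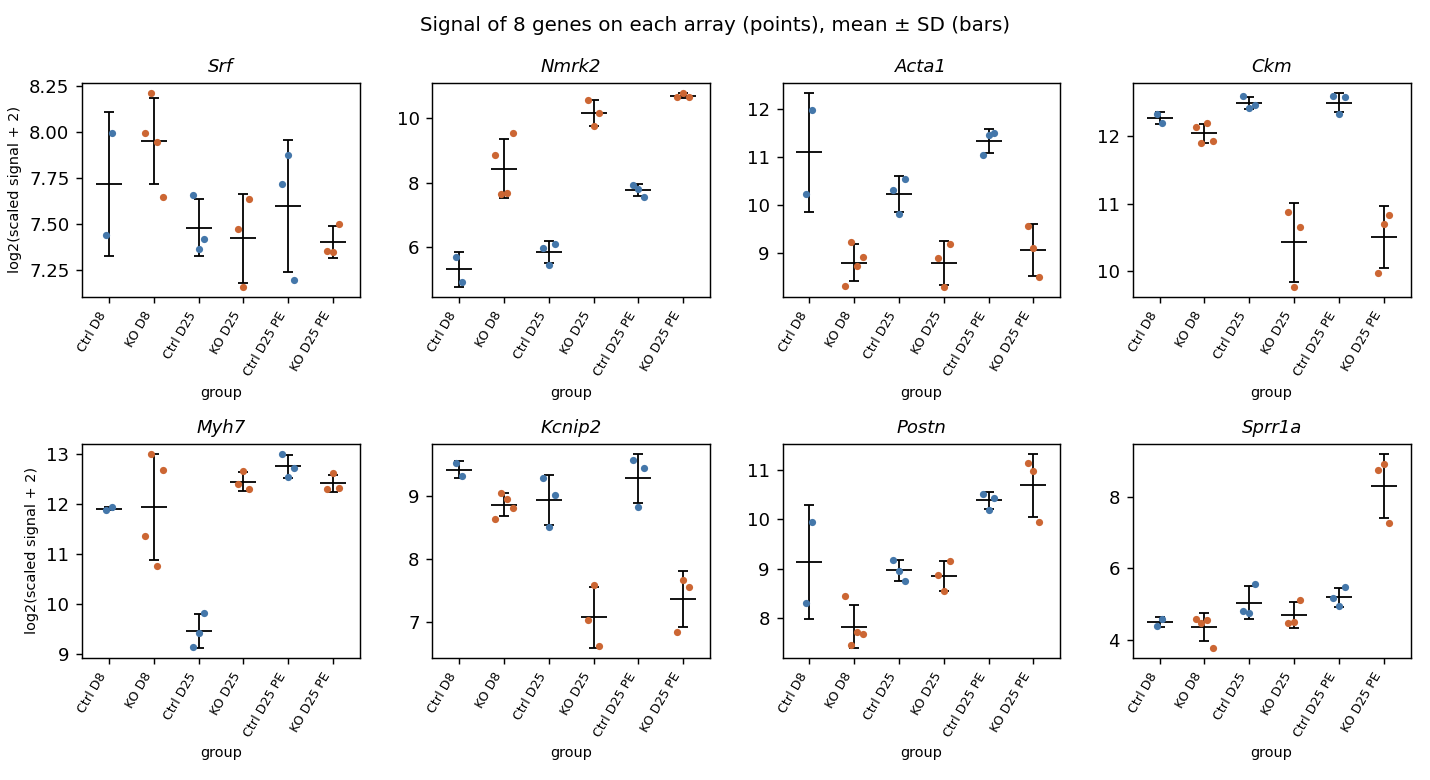
Log2 (scaled signal + 2) of Srf, Nmrk2, Acta1, Ckm, Myh7, Kcnip2, Postn and Sprr1a on each of the 18 arrays (points, control in blue and SRFHKO in orange), with the mean and SD of each group as bars; each panel has its own axis range. Ckm lay at 10.43 ± 0.59 (SD, n = 3) in SRFHKO and 12.49 ± 0.09 (SD, n = 3) in control hearts at day 25, and Myh7 was low in control hearts at day 25 without PE, at 9.45 ± 0.34 (SD, n = 3).

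At day 8 the ventricles of SRFHKO mice had 8.69-fold more Nmrk2 transcript than control ventricles and 4.96-fold less Acta1. Nmrk2, a kinase that phosphorylates nicotinamide riboside, a step towards NAD, rose by 3.12 ± 0.39 on the log2 scale (limma adjusted p = 0.00221), and Acta1, skeletal alpha-actin and a known SRF target, fell by 2.31 ± 0.38 (adjusted p = 0.0196). In all, 8 of 12610 genes passed the threshold, 6 higher and 2 lower. The other fall was Hacd1, a dehydratase of very long chain fatty acid synthesis (-0.90 ± 0.15, adjusted p = 0.0261). The other rises were Zfp207 (1.08 ± 0.18, adjusted p = 0.0196), Lsm6 (0.75 ± 0.13, adjusted p = 0.0370), Esr1, Hspbap1 and 2900093K20Rik. For the last 3 both control arrays lay below the filter limit of 3.58, so only a lower bound can be given: Esr1 was at least 27.1-fold higher (adjusted p = 0.0119), Hspbap1, from an _x_at probe set, at least 2.35-fold (0.00842) and 2900093K20Rik at least 2.52-fold (0.0111). The Esr1 change was seen by 1 probe set; the other Esr1 probe set above the filter differed by -0.15 ± 0.37 (adjusted p = 0.941, adjusted over all probe sets). For Zfp207, Lsm6, Hspbap1 and 2900093K20Rik, the 2 control arrays of day 8 lay below every other array, day 25 controls included. Zfp207 lay at 7.42 and 6.89 there and Lsm6 at 7.71 and 7.55, against 8.18 or above on all other arrays for each. For these genes a rise in SRFHKO hearts and low values in 2 control arrays cannot be told apart. Among the core genes that did not pass, log2 differences were -0.73 ± 0.17 for the natriuretic peptide Nppa (adjusted p = 0.191), -0.81 ± 0.21 for the smooth muscle actin Acta2 (0.235) and -1.30 ± 0.36 for the matrix protein Postn (0.260). The Postn difference was -2.11 ± 0.37 without control replicate 1 (adjusted p = 0.0166) and -0.48 ± 0.37 without control replicate 2 (0.969).

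Some signs of RNA quality moved with genotype at day 8. The scaled signal of 18S rRNA was 2426 and 3069 in control and 705 to 1402 in SRFHKO arrays. The Gapdh 3'/5' ratio was 1.02 and 1.01 in control and 0.850 to 0.936 in SRFHKO arrays. Neither overlapped between the genotypes. The Actb 3'/5' ratio did overlap, at 2.07 and 2.52 in control and 1.52 to 2.12 in SRFHKO arrays. Among the fixed lists at day 8, the SRF-dependent actin and cytoskeletal genes had a median log2 difference of -0.12 over 29 measured members. Adjusted p was 0.00944 with camera and adjusted p = 0.604 with an estimated correlation. Of these, 1 member (Acta1) fell over all genes tested and 4 were lower when adjusted over the list alone. The 15 measured fetal cardiac genes had a median of -0.36 with the same counts, 1 and 4. Adjusted p was 0.00944 with camera and adjusted p = 0.604 with an estimated correlation. Extracellular matrix genes had a median of -0.32 (camera adjusted p = 1.16e-05; adjusted p = 0.604 with an estimated correlation); 0 of 40 passed limma over all genes, 11 were lower at an unadjusted p under 0.05 and 4 when adjusted over the list alone. Macrophage and monocyte markers lay lower by a median of -0.40 over 18 members. Adjusted p was 0.000973 with camera and adjusted p = 0.604 with an estimated correlation. Endoplasmic reticulum chaperones had a median of 0.44 over 17 members (camera adjusted p = 0.00239; adjusted p = 0.763 with an estimated correlation) and cytosolic ribosomal proteins a median of 0.18 over 31. Adjusted p was 0.000582 with camera and adjusted p = 0.750 with an estimated correlation. Camera also called fibroblast, adipocyte, skeletal muscle and cardiomyocyte markers and oxidative phosphorylation genes, with medians of -0.26, -0.58, -0.49, -0.09 and -0.06. Their adjusted p values ran from 0.0161 to 0.0426, and their smallest adjusted p was 0.604 with an estimated correlation; quantile normalisation ended all 5 of these calls. Its medians were -0.25 for fibroblast (adjusted p = 0.0709), -0.59 for adipocyte (0.0509), -0.54 for skeletal muscle (0.0509) and -0.03 for cardiomyocyte markers (0.513) and -0.01 for oxidative phosphorylation genes (0.675). The fibroblast call also ended without control replicate 2 or SRFHKO replicate 2 or 3 (medians from -0.23 to -0.16). The adipocyte call (-0.51 to -0.42) and the skeletal muscle call (-0.65 to -0.36) ended without either control array or SRFHKO replicate 3. The calls of cardiomyocyte markers and oxidative phosphorylation genes ended without SRFHKO replicate 1 or 2 (-0.07 to -0.05), and without control replicate 1, where the medians were 0.04 and 0.05. A pseudocount of 9.40 ended the calls of skeletal muscle (median -0.37, adjusted p = 0.0519), adipocyte (-0.38, 0.0754) and cardiomyocyte markers (-0.09, 0.0519), and no filter those of skeletal muscle (-0.23, 0.0776) and adipocyte markers (-0.48, 0.0619). A fit on the compared groups alone ended those of fibroblast (adjusted p = 0.0509) and cardiomyocyte markers (0.114) and oxidative phosphorylation genes (0.0509), with their medians as above.

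With 2 control arrays, the day 8 count rested on single hearts. It was 51 without control replicate 1, 7 of the 8 among them, 4 without SRFHKO replicate 1 and 2 without SRFHKO replicate 3, all of them among the 8. Without control replicate 2 it was 3, with 0 of the 8 among them, and in a fit on the compared groups alone it was 2, again with 0 of the 8; there Nmrk2 had an adjusted p of 0.0784 and Acta1 of 0.137. Without control replicate 2, Nmrk2 (2.73 ± 0.49, adjusted p = 0.0980), Esr1 (0.112) and Acta1 (-1.43 ± 0.38, 0.310) missed the threshold. Acta1 also missed it without SRFHKO replicate 1 (adjusted p = 0.0778) or 3 (0.0535), and Esr1 without SRFHKO replicate 3 (0.0532). The same control array decided list calls: without control replicate 2 the medians were -0.19 for the matrix list (adjusted p = 0.0949), 0.09 for ribosomal proteins (0.347), -0.08 for macrophage markers (0.645) and -0.10 for SRF-dependent genes (0.199). SRF-dependent genes also missed the threshold without SRFHKO replicate 2 (median -0.07, adjusted p = 0.0528). For chaperones the median was 0.09 without control replicate 1 (adjusted p = 0.673) and 0.20 without SRFHKO replicate 2 (0.196), and for fetal genes it was -0.08 without SRFHKO replicate 3 (0.0636).

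At day 25 without PE, Nmrk2 was 19.96-fold higher in SRFHKO than in control ventricles and the beta-myosin heavy chain Myh7 was 7.99-fold higher, while muscle creatine kinase (Ckm) was 4.17-fold lower and Kcnip2, a subunit of the transient outward potassium channel, 3.65-fold lower. The log2 differences were 4.32 ± 0.36 for Nmrk2 (limma adjusted p = 5.56e-06), 3.00 ± 0.38 for Myh7 (0.000562), -2.06 ± 0.22 for Ckm (0.000134) and -1.87 ± 0.25 for Kcnip2 (0.000975). Acta1 fell by 1.43 ± 0.36 (adjusted p = 0.0408). In all, 295 of 12610 genes passed, 159 higher and 136 lower, of which 26 and 32 differed at least 2-fold.

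The 10 rises named by the rule at day 25 without PE included, besides Nmrk2 and Myh7, the fast skeletal light chain Myl1 (2.35 ± 0.44) and Rbm45 (2.33 ± 0.43). For the other 6, some of the 3 control arrays lay below the filter limit, and folds against control levels raised to that limit are lower bounds. With 2 control arrays below it, Esr1 was at least 42.05-fold (adjusted p = 0.000562), Smn1 at least 2.63-fold and Zfp14 at least 2.35-fold higher. With 1 below it, the glycosyltransferase Gcnt1 was at least 3.27-fold, Zfp385b at least 3.12-fold and Gm32688 at least 3.01-fold higher. Adjusted p of these 5 besides Esr1 ran from 0.00209 for Gcnt1 to 0.0312 for Gm32688. For Myh7, Zfp385b and Gcnt1, the 3 control arrays lay below every other array, controls of day 8 and with PE included. Rbm45 lay at 7.19, 5.38 and 4.31 there, against 7.17 or above on all other arrays. Smn1 lay at 4.97, 2.74 and 3.36, against 4.92 or above. Gcnt1 also passed with PE. For Myh7, Zfp385b, Rbm45 and Smn1, a rise with deletion and low values in this control group cannot be told apart. The Esr1 change was again seen by 1 probe set, while the other differed by -0.29 ± 0.35 (adjusted p = 0.712). The 10 falls named by the rule included Igha, an immunoglobulin heavy chain gene (-3.65 ± 0.88), Zfp30 (-3.40 ± 0.44), the interferon-induced GTPases Irgm2 (-2.56 ± 0.48) and Igtp (-2.32 ± 0.39), Ckm, Ptges3l (-2.05 ± 0.24) and Kcnip2. The other 3 lay below the filter limit in all 3 SRFHKO arrays, where Stbd1 was at least 6.13-fold, Gm10512 at least 2.39-fold and Nrg2 at least 1.98-fold lower than in control hearts. Stbd1 varied widely between hearts with PE, from 3.01 to 6.98 in SRFHKO and from 3.75 to 6.63 in control hearts. The adjusted p of the 10 ran from 0.000134 for Ckm to 0.0395 for Gm10512. Of the core genes, the natriuretic peptides differed by -0.16 ± 0.16 for Nppa (adjusted p = 0.636) and -0.05 ± 0.28 for Nppb (0.943), and Ankrd1 by 0.52 ± 0.19 (0.145). The alpha-myosin heavy chain Myh6 (-0.35 ± 0.10, adjusted p = 0.0626) and cardiac actin Actc1 (-0.37 ± 0.11, 0.0773) did not pass, and neither did Postn (-0.11 ± 0.34, 0.897) nor the NAD enzyme Nampt (-0.10 ± 0.15, 0.779).

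Among lists of energy metabolism at day 25 without PE, camera called oxidative phosphorylation, TCA cycle and fatty acid oxidation genes, and did not call glycolysis (adjusted p = 0.214) or creatine kinase and energy transfer (0.259). The Gapdh 3'/5' ratio, a sign of RNA quality, was 0.868 to 0.945 in control and 0.820 to 0.835 in SRFHKO arrays of these groups, without overlap. The Actb 3'/5' ratio overlapped, at 2.00 to 2.03 in control and 1.83 to 2.02 in SRFHKO arrays. Of 68 measured oxidative phosphorylation genes, 9 fell and 1, Cox8a, rose (0.62, adjusted p = 0.00361). The falls included Uqcr11 (-0.44), Ndufv3 (-0.50) and Uqcrc1 (-0.45). Adjusted over the list alone 44 were lower and 1 higher, and the median was -0.26. Adjusted p was 3.43e-13 with camera and adjusted p = 0.846 with an estimated correlation. The TCA cycle list had 3 falls among 19 members, citrate synthase Cs (-0.39), Suclg1 (-0.36) and Sdhb (-0.44), with 7 lower when adjusted over the list alone and a median of -0.21. Adjusted p was 0.00107 with camera and adjusted p = 0.846 with an estimated correlation. Fatty acid oxidation genes had 1 fall among 33, Acadvl (-0.39), 2 lower when adjusted over the list alone, and a median of -0.19. Adjusted p was 0.00622 with camera and adjusted p = 0.973 with an estimated correlation. Markers of cardiomyocytes had a median of -0.25 with 2 falls among 16, Tnnc1 and Myl3, and 7 lower when adjusted over the list alone. Adjusted p was 0.000332 with camera and adjusted p = 0.973 with an estimated correlation. Markers of endothelial cells had a median of -0.24 with 1 fall among 17, Cldn5 (-0.81), and 6 when adjusted over the list alone. Adjusted p was 0.000920 with camera and adjusted p = 0.398 with an estimated correlation. The 3 measured lung markers had a median of -0.89, with 1 fall, counted the same over the list alone. This was Napsa, which lay below the filter limit in all 3 SRFHKO arrays and was at least 1.56-fold lower; with Napsa at that limit the median was -0.64. Adjusted p was 0.0487 with camera and adjusted p = 0.742 with an estimated correlation. Quantile normalisation ended the calls of cardiomyocyte and lung markers, TCA cycle and fatty acid oxidation genes, and the medians of these lists stayed below 0, at -0.02, -0.73, -0.13 and -0.19. The lung call also ended with no filter (median -0.60, adjusted p = 0.311) and with no pseudocount (-0.99, 0.0515). Brightness as a covariate, chosen after seeing the data, ended those of cardiomyocyte and lung markers and fatty acid oxidation genes (medians -0.05, -0.58 and -0.11), and without control day 25 replicate 3 the lung call ended (median -0.59, adjusted p = 0.141), as it did without SRFHKO replicate 1 (-1.12, 0.0603) or 2 (-0.71, 0.0786).

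Within other lists at day 25 without PE, single members passed while the list did not. In the sarcomere list of 25 genes, Myh7 rose while cardiac troponin C Tnnc1 (-0.62, adjusted p = 0.00218), the ventricular light chain Myl3 (-0.73, 0.00322) and the M-line protein Myom1 (-0.51, 0.0263) fell (camera adjusted p = 0.259, with 4 higher and 8 lower when adjusted over the list alone). The list of SRF-dependent actin and cytoskeletal genes held 1 rise, Fhl1 (0.64), and 1 fall, Acta1, among 29 members, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.316). In the list of SRF cofactors and cardiac transcription factors, the SRF cofactor Myocd (0.78) and Tbx20 (0.76) rose, with the same count of 2 over the list alone (camera adjusted p = 0.574). Among intercalated disc and costamere genes, connexin 43 (Gja1, 0.74) and N-cadherin (Cdh2, 0.46) rose, 2 over the list alone as well (camera adjusted p = 0.228). Of 23 interferon response genes, Tap1 (-1.76), Gbp2 (-1.30) and Psmb9 (-1.35) fell, with 4 lower when adjusted over the list alone, while the median was -0.03 (camera adjusted p = 0.375). Grk5, a kinase of G protein-coupled receptors (1.30), glutathione peroxidase Gpx3 (0.94) and ceruloplasmin (Cp, 0.93) rose as well. For the fetal cardiac genes the median was -0.16 and the mean 0.04, with 2 higher and 1 lower of 15 and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.998).

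The day 25 count of 295 was 164 without control replicate 1 (139 of the 295 among them), 99 without control replicate 3 (85), 96 without SRFHKO replicate 2 (81) and 56 without SRFHKO replicate 3 (56). Nmrk2, Myh7, Ckm, Kcnip2 and Tnnc1 passed under every alternative run for named genes. Acta1 missed the threshold without control replicate 1 or 3 or any SRFHKO array (adjusted p from 0.0575 without SRFHKO replicate 1 to 0.167 without SRFHKO replicate 2). With brightness as a covariate, 39 genes passed. All 295 kept their direction, the median absolute log2 difference of the 295 moved from 0.68 to 0.61 and their median standard error from 0.15 to 0.18, and 35 of them still passed.

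The deletion effects, meaning the differences of SRFHKO from control hearts, shared 4 called genes between day 8 and day 25 without PE. Nmrk2 and Esr1 rose at both days (2 genes against 0.0757 expected of independent lists) and Acta1 and Hacd1 fell at both (2 against 0.0216). Across the 12610 genes, which are not independent replicates, the log2 differences of the 2 days correlated with Pearson's r = 0.0923 and Spearman's rho = 0.0884. Among the 295 genes called at day 25, 203 (68.8%) had the same sign at day 8. No arrays were common to the 2 contrasts. In the test of the difference itself, 0 genes passed (limma, smallest adjusted p = 0.115; 1407 genes at an unadjusted p under 0.05). The 5 smallest p belonged to Ckm (-1.83 ± 0.32), Myh7 (2.96 ± 0.55), Mapre2 (1.23 ± 0.23), Mib1 (1.07 ± 0.20) and 2900093K20Rik, given as values and not as calls. No size is given for the last, since both of its control arrays at day 8 lay below the filter limit. The count of 0 was 15 without control day 8 replicate 1, 3 without control day 8 replicate 2 or SRFHKO day 25 replicate 1, 2 without SRFHKO day 8 replicate 2 and 1 without control day 25 replicate 1. Camera called 2 lists in this interaction, oxidative phosphorylation genes with a median of -0.18 (adjusted p = 0.000176; adjusted p = 0.811 with an estimated correlation) and endothelial markers with a median of -0.33 (adjusted p = 0.00447; adjusted p = 0.602 with an estimated correlation). The first of these ended without control day 8 replicate 2 (median -0.08, adjusted p = 0.703), after quantile normalisation (-0.07, 0.159) and with brightness as a covariate (-0.08, 0.366).

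In control hearts, PE was followed by 9.93-fold more Myh7, 2.57-fold more of the inducible chaperone Hsp90aa1 and 1.83-fold more of the actin regulator Enah. The log2 rises were 3.31 ± 0.38 for Myh7 (limma adjusted p = 0.000758), 1.36 ± 0.21 for Hsp90aa1 (0.0201), 0.88 ± 0.14 for Enah (0.0280) and 0.59 ± 0.10 for 1700025G04Rik (0.0459). These were the 4 genes of 12610 that passed. At an unadjusted p under 0.05 there were 1328 genes. Thbs4, the fifth by p (1.14 ± 0.21, adjusted p = 0.0676), Nmrk2 (1.94 ± 0.36, 0.0676), Postn (1.42 ± 0.34, 0.191), Acta1 (1.11 ± 0.36, 0.261) and Nppb (0.78 ± 0.28, 0.318) did not pass.

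Extracellular matrix genes had a median of 0.19 with PE in control hearts (camera adjusted p = 0.000267; adjusted p = 0.794 with an estimated correlation); 0 of 40 passed limma over all genes, 8 were higher and 1 lower at an unadjusted p under 0.05, and 6 were higher and 1 lower when adjusted over the list alone. Fatty acid oxidation genes had a median of -0.24 (camera adjusted p = 2.01e-06; adjusted p = 0.794 with an estimated correlation); 0 of 33 passed over all genes by limma, 11 were lower at an unadjusted p under 0.05 and 6 when adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.14 (camera adjusted p = 3.07e-06; adjusted p = 0.794 with an estimated correlation), a call that quantile normalisation ended (median -0.03, adjusted p = 0.126). The fetal cardiac genes, with Myh7 as the 1 that rose of 15 and 4 when adjusted over the list alone, had a median of 0.01 and a mean of 0.34, and quantile normalisation ended their call (median -0.01, adjusted p = 0.102). Adjusted p was 0.0252 with camera and adjusted p = 0.794 with an estimated correlation. Endoplasmic reticulum chaperones had a median of 0.29 (camera adjusted p = 0.00856; adjusted p = 0.794 with an estimated correlation) and endothelial markers a median of -0.20. Adjusted p was 0.0198 with camera and adjusted p = 0.794 with an estimated correlation. The interferon response list had a median of 0.60 (camera adjusted p = 0.0115; adjusted p = 0.794 with an estimated correlation), and it was -0.05 without control with PE replicate 3 (adjusted p = 0.972). This call also ended without control with PE replicate 1 (median 0.56, adjusted p = 0.156) or control day 25 replicate 2 (0.55, 0.0610) or 3 (0.61, 0.0709). The call of the matrix list ended without control day 25 replicate 3, with a median of 0.04 (adjusted p = 0.224), as did that of chaperones (median 0.16, adjusted p = 0.224), which also ended without control with PE replicate 2 (0.20, 0.0692). The endothelial call ended without control day 25 replicate 1 (median -0.18, adjusted p = 0.108) or 2 (-0.16, 0.0614) or control with PE replicate 1 (-0.15, 0.202). The fetal call ended without the same 3 arrays, at adjusted p = 0.0795, 0.147 and 0.0941, with medians of 0.04, -0.05 and 0.06.

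The count of 4 was 7 without control day 25 replicate 1, 3 of the 4 among them, and 1 without control day 25 replicate 2 or without replicate 1 or 3 of control with PE. Myh7 passed under every alternative run for named genes. Hsp90aa1, Enah and 1700025G04Rik missed the threshold without control day 25 replicate 2 (adjusted p = 0.0999 for each) or 3 or without control with PE replicate 1 (0.167 for each) or 3; 1700025G04Rik also missed it without control day 25 replicate 1 (0.0723) or control with PE replicate 2 (0.0604).

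In SRFHKO hearts, PE was followed by 12.1-fold more Sprr1a, a small proline-rich protein, and by more transcript of 6 of 40 extracellular matrix genes. Sprr1a rose by 3.59 ± 0.36 on the log2 scale (limma adjusted p = 9.24e-05), periostin (Postn) by 1.83 ± 0.34 (0.0246), the collagen chain Col8a1 by 1.76 ± 0.25 (0.00651), Tgfb2 by 1.38 ± 0.26 (0.0254) and the calcineurin regulator Rcan1 by 1.63 ± 0.27 (0.0167). Eci1, an enzyme of fatty acid oxidation, fell by 0.83 ± 0.15 (0.0238) and muscle fructose bisphosphatase Fbp2 by 1.52 ± 0.28 (0.0246). In all, 37 genes passed, 23 higher and 14 lower. The other large rises were Bcr (1.65 ± 0.32), Uck2 (1.21 ± 0.20), filamin C (Flnc, 1.19 ± 0.25), Thbs4 (1.19 ± 0.21) and Bcl2 (0.998 ± 0.170). The other large falls were Lgi1 (-1.44 ± 0.27), Dhrs7c (-1.09 ± 0.18), Gpat3 (-0.95 ± 0.17), the angiotensin receptor Agtr1a (-0.84 ± 0.16), Dhrs11 (-0.83 ± 0.15), the phosphatase Dusp1 (-0.77 ± 0.13), Ccrl2 (-0.67 ± 0.14) and Rmdn1 (-0.58 ± 0.11). Myh7 differed by -0.03 ± 0.38 (adjusted p = 0.990), Nppb by 1.08 ± 0.28 (0.113) and Ccn2 by 1.19 ± 0.31 (0.111), none of which passed.

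The matrix list moved most with PE in SRFHKO hearts among the lists with a camera call, with a median of 0.66 over 40 members. Adjusted p was 6.52e-17 with camera and adjusted p = 0.179 with an estimated correlation. Of its members 6 rose over all genes, among them Postn, Col8a1, Thbs4 and Tgfb3 (0.84), and 16 when adjusted over the list alone. Fibroblast markers, which share Postn and collagen genes with it, had a median of 0.33, with 1 rise of 15 and 4 when adjusted over the list alone. Adjusted p was 0.00541 with camera and adjusted p = 0.649 with an estimated correlation. Fatty acid oxidation genes had a median of -0.34, with 3 falls of 33, Eci1, Decr1 (-0.53) and Ech1 (-0.49), and 19 when adjusted over the list alone. Adjusted p was 6.52e-17 with camera and adjusted p = 0.110 with an estimated correlation. The TCA cycle list had a median of -0.21, with 0 of 19 past limma's threshold over all genes, 10 lower at an unadjusted p under 0.05 and 9 when adjusted over the list alone. Adjusted p was 6.64e-07 with camera and adjusted p = 0.245 with an estimated correlation. Hypertrophy and calcineurin signalling genes had a median of 0.16, with 1 rise of 22, Rcan1, and 4 higher and 1 lower when adjusted over the list alone. Adjusted p was 0.00492 with camera and adjusted p = 0.110 with an estimated correlation. Oxidative phosphorylation genes had a median of -0.18 (camera adjusted p = 2.30e-15; adjusted p = 0.560 with an estimated correlation), ribosomal proteins of -0.16 (2.57e-05; adjusted p = 0.649 with an estimated correlation) and cardiomyocyte markers of -0.15 (0.00162; adjusted p = 0.784 with an estimated correlation), the last of which quantile normalisation ended (median -0.01, adjusted p = 0.741). Endoplasmic reticulum chaperones had a median of 0.41 (camera adjusted p = 0.000405; adjusted p = 0.760 with an estimated correlation) and intercalated disc and costamere genes of 0.11 (0.0189; adjusted p = 0.182 with an estimated correlation).

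The count of 37 was 7, 5 and 2 without SRFHKO day 25 replicate 1, 2 and 3, with 5, 5 and 2 of the 37 among them, and 83 and 1 without SRFHKO with PE replicate 1 and 2, with 25 and 1 among them. Sprr1a passed under every alternative run for named genes. Postn missed the threshold without any of these 5 arrays (adjusted p from 0.0568 without SRFHKO with PE replicate 1 to 0.163 without SRFHKO with PE replicate 2), Col8a1 without SRFHKO with PE replicate 2 (0.0667), and Rcan1 without SRFHKO day 25 replicate 1 (0.0775) or 3 (0.0769) or SRFHKO with PE replicate 2 (0.129). The cardiomyocyte call ended without SRFHKO day 25 replicate 1 (median -0.09, adjusted p = 0.0526). The fibroblast call ended without SRFHKO day 25 replicate 2 (0.17, 0.196) or SRFHKO with PE replicate 1 (0.24, 0.0795), and the intercalated disc call without replicate 1 of SRFHKO (0.13, 0.0706) or of SRFHKO with PE (0.07, 0.0636).

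The response to PE differed between the genotypes for 3 genes by the interaction test, Sprr1a, Prkab2 and Myh7. Myh7 rose with PE in control hearts, from 9.45 ± 0.34 to 12.77 ± 0.23 (SD, n = 3 each), and lay at 12.45 ± 0.18 without and 12.42 ± 0.17 with PE in SRFHKO hearts, an interaction of -3.34 ± 0.54 (limma adjusted p = 0.0278). Sprr1a lay between 4.71 ± 0.36 and 5.19 ± 0.27 in 3 of the 4 groups of day 25 and at 8.30 ± 0.90 in SRFHKO hearts with PE (interaction 3.45 ± 0.51, adjusted p = 0.0271). Prkab2, a subunit of AMP-activated protein kinase, had an interaction of 1.07 ± 0.17 (adjusted p = 0.0278). Itga9 (1.23 ± 0.25, adjusted p = 0.240) and Gpr22 (-2.14 ± 0.42, adjusted p = 0.237) did not pass. Nmrk2 (-1.40 ± 0.51, adjusted p = 0.586) and Postn (0.41 ± 0.48, adjusted p = 0.880) gave no call either. Myh7 missed the threshold after quantile normalisation (-3.09 ± 0.56, adjusted p = 0.134), and the count of 3 was 0 without control day 25 replicate 2, control with PE replicate 1, 2 or 3, SRFHKO day 25 replicate 2 or SRFHKO with PE replicate 2, and 1 without SRFHKO day 25 replicate 1 or 3 or SRFHKO with PE replicate 3, against 7, the 3 among them, without SRFHKO with PE replicate 1.

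Between the PE responses of the 2 genotypes, 1 rise was common, 1700025G04Rik (0.0073 expected of independent lists), and 34 of the 37 genes called in SRFHKO hearts had the same sign in control hearts. Across all genes the 2 responses correlated with Pearson's r = 0.154 and Spearman's rho = 0.142, with no array in common.

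**Figure D2:**
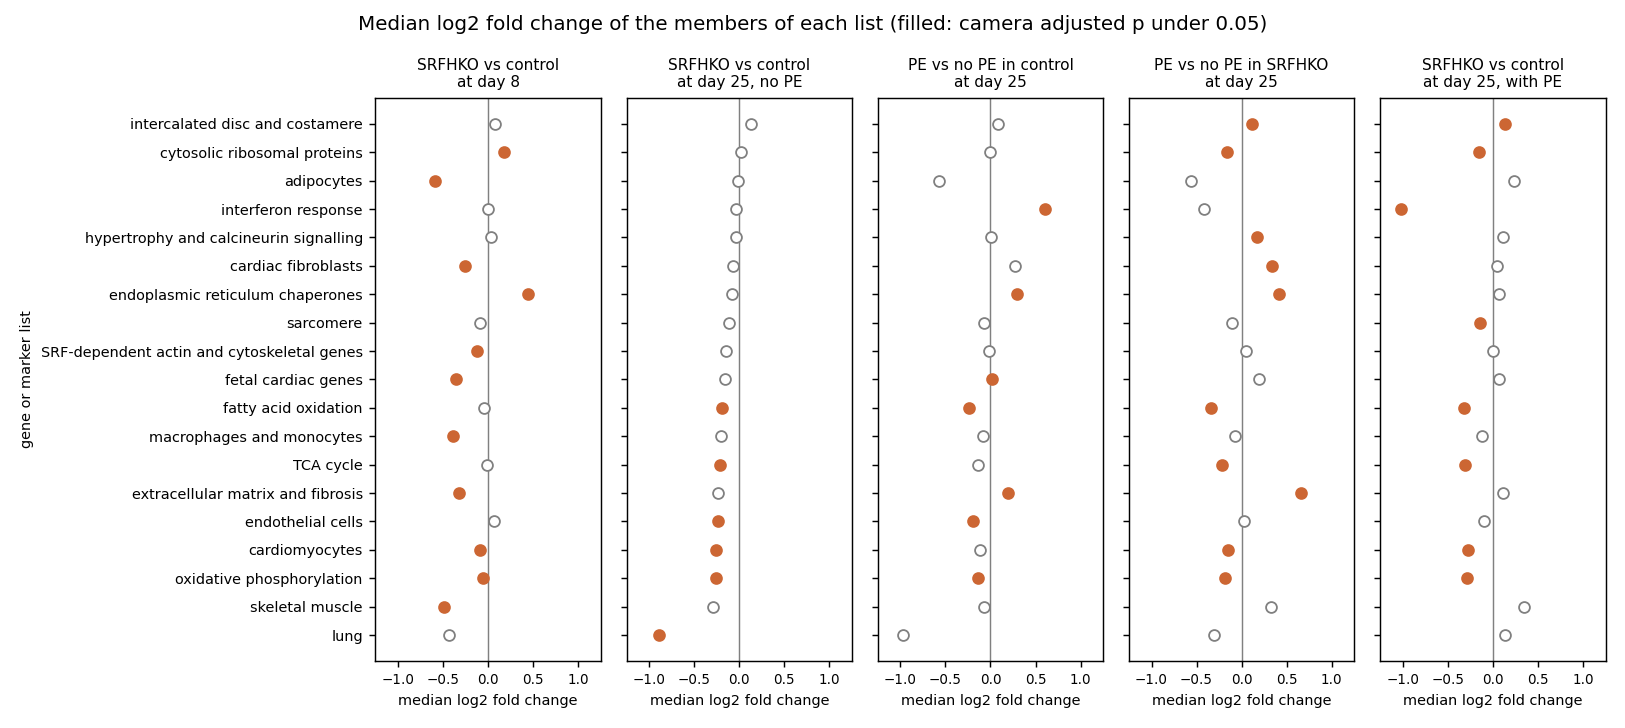
Median log2 fold change (horizontal axes) of the measured members of each list that camera called in at least 1 of the 5 comparisons shown, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points for the rest. The matrix list reached 0.66 with PE in SRFHKO hearts and the interferon list -1.02 in SRFHKO against control hearts with PE; 0 of these calls passed with an estimated correlation.

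Under PE at day 25, SRFHKO ventricles had 8.60-fold more Sprr1a and 7.59-fold more Nmrk2 than control ventricles, and 4.85-fold less Acta1, 4.02-fold less of the integrin-binding muscle protein melusin (Itgb1bp2) and 3.98-fold less Ckm. The log2 differences were 3.10 ± 0.36 for Sprr1a (limma adjusted p = 0.000194), 2.92 ± 0.36 for Nmrk2 (0.000402), -2.28 ± 0.36 for Acta1 (0.00255), -2.01 ± 0.21 for Itgb1bp2 (0.000132) and -1.99 ± 0.22 for Ckm (0.000194). Kcnip2 fell by 1.93 ± 0.25 (adjusted p = 0.000730), and Myh7, at the same time, differed by -0.34 ± 0.38 (0.754). In all, 206 genes passed, 93 higher and 113 lower, 26 and 33 of them at least 2-fold.

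The remaining rises named under PE included Lrp11 (1.74 ± 0.26), Phlda1 (1.74 ± 0.29), Gm30873 (1.72 ± 0.40) and Pwwp3b (1.69 ± 0.26). Amph and the metalloprotease Adam12 lay below the filter limit in all 3 control arrays and were at least 2.80-fold (adjusted p = 0.0129) and 2.32-fold (0.0197) higher in SRFHKO hearts. With 1 of the 3 control arrays below it, Esr1 was at least 8.60-fold (0.0233) and Psca at least 6.47-fold higher (0.0199). The remaining falls included Amacr (-2.35 ± 0.55), Zfp30 (-2.08 ± 0.44), Wfdc17 (-1.90 ± 0.35) and B3galt5 (-1.90 ± 0.36). Amacr varied widely within the groups of day 25 without PE, from 6.03 to 8.24 in control and from 5.48 to 7.30 in SRFHKO hearts. A930006K02Rik lay below the limit in all 3 SRFHKO arrays and was at least 3.05-fold lower (adjusted p = 0.0490, the highest among these genes). Lrrc27 lay below it in 1 of the 3 and was at least 3.19-fold lower (0.0486). Natriuretic peptides and Postn gave no call, with differences of -0.07 ± 0.16 for Nppa, 0.25 ± 0.28 for Nppb and 0.31 ± 0.34 for Postn.

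Oxidative phosphorylation genes were again lower, with 15 falls and 0 rises among 68 by limma over all genes (1 higher at an unadjusted p under 0.05), such as Ndufa6 (-0.49) and Uqcrfs1 (-0.46), 55 lower and 1 higher when adjusted over the list alone, and a median of -0.29. Adjusted p was 6.07e-26 with camera and adjusted p = 0.280 with an estimated correlation. TCA cycle genes had a median of -0.31, with 2 falls of 19, Cs (-0.43) and Suclg1 (-0.50), and 13 when adjusted over the list alone. Adjusted p was 3.23e-10 with camera and adjusted p = 0.245 with an estimated correlation. Fatty acid oxidation genes had a median of -0.32, with 4 falls of 33, the transcription factor Ppara (-1.23), Acadvl (-0.51), Eci1 (-0.77) and Etfb (-0.52), and 15 when adjusted over the list alone. Adjusted p was 4.61e-10 with camera and adjusted p = 0.280 with an estimated correlation. The sarcomere list had 4 falls of 25, Tnnc1 (-0.73), Myl3 (-0.81), Ldb3 (-0.46) and Myom1 (-0.47), with 1 higher and 7 lower when adjusted over the list alone and a median of -0.14, which turned to 0.03 after quantile normalisation. Adjusted p was 0.000729 with camera and adjusted p = 0.536 with an estimated correlation. Cardiomyocyte markers had a median of -0.27 with 2 falls of 16 and 8 when adjusted over the list alone. Adjusted p was 5.29e-08 with camera and adjusted p = 0.536 with an estimated correlation. Intercalated disc and costamere genes had a median of 0.14 (camera adjusted p = 0.0117; adjusted p = 0.245 with an estimated correlation), and cytosolic ribosomal proteins a median of -0.16. Adjusted p was 0.00693 with camera and adjusted p = 0.809 with an estimated correlation. All 23 interferon response genes were lower, with a median of -1.02 (camera adjusted p = 4.61e-10; adjusted p = 0.536 with an estimated correlation); 0 passed limma over all genes, 18 were lower at an unadjusted p under 0.05 and 16 when adjusted over the list alone. Gpx3 (1.34) and Grk5 (1.38) rose as they had without PE, while the antioxidant genes Sod2 (-0.55) and Mt1 (-1.03) fell. Quantile normalisation ended the calls of cardiomyocyte markers (median -0.03), sarcomere genes (0.03) and ribosomal proteins (-0.01), and brightness as a covariate, chosen after seeing the data, those of the last 2 (-0.05 and -0.06) and of intercalated disc and costamere genes (median 0.13, adjusted p = 0.109). The ribosomal call also ended without SRFHKO with PE replicate 2 (median -0.11, adjusted p = 0.0724).

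**Figure D3:**
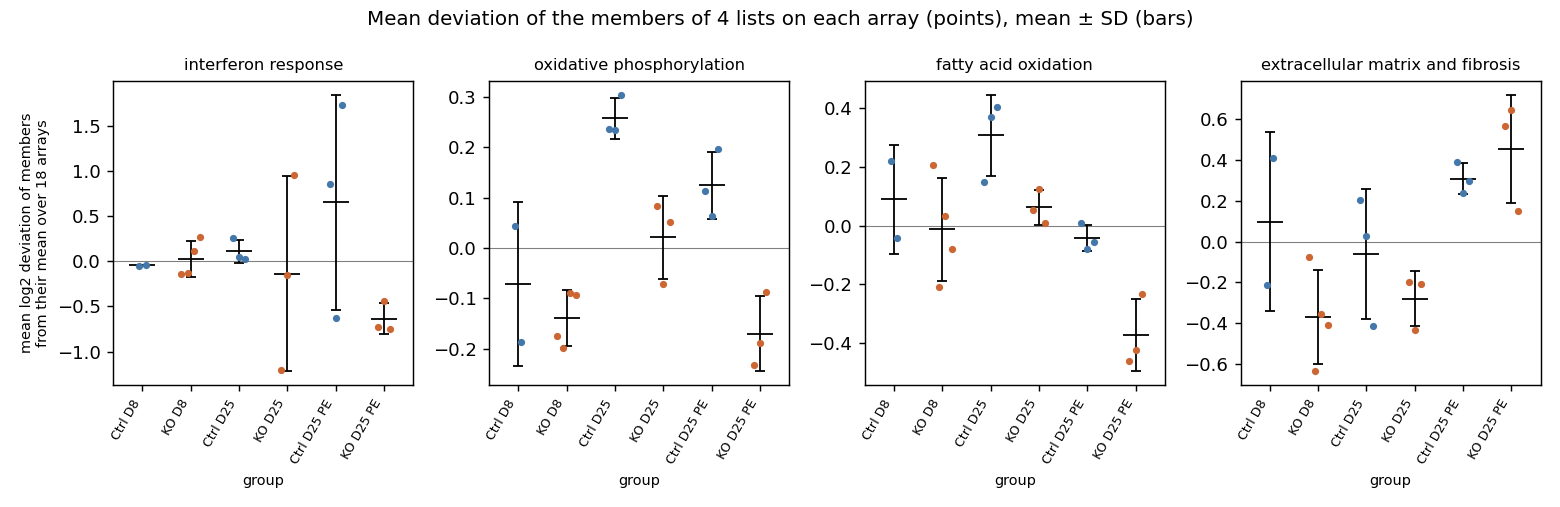
Mean log2 deviation of the members of 4 lists from their mean over the 18 arrays, for each array (points, control in blue and SRFHKO in orange), with the mean and SD of each group as bars; each panel has its own axis range. For the interferon response list the 3 hearts of control with PE lay at 0.86, -0.63 and 1.73, and those of SRFHKO with PE at -0.72, -0.44 and -0.75.

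The count of 206 was 81 without control with PE replicate 1 (75 of the 206 among them), 77 without control with PE replicate 3 (69) and 47 without SRFHKO with PE replicate 2 (45). Nmrk2, Acta1, Ckm, Kcnip2, Itgb1bp2, Sprr1a, Tnnc1 and Myl3 passed under every alternative run for named genes. With brightness as a covariate 56 genes passed, 48 of the 206 among them; all 206 kept their direction, and the median absolute log2 difference moved from 0.71 to 0.68 and the median standard error from 0.15 to 0.17.

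The deletion effects without and with PE shared 29 rises (1.17 expected of independent lists) and 36 falls (1.22 expected), and no gene was called in opposite directions. Of the 206 genes called with PE, 193 (93.7%) had the same sign without PE. Across all genes the log2 differences correlated with Pearson's r = 0.308 and Spearman's rho = 0.308, again with no array in common. The shared genes included Nmrk2, Esr1, Grk5, Gpx3, Gcnt1 and Cp among the rises and Acta1, Ckm, Kcnip2, Itgb1bp2, Tnnc1, Myl3, Myom1, Cs and Zfp30 among the falls.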

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

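The tests of the Esr1, Myh7 and interferon patterns were chosen only after the result was seen, while the counts over other splits of the arrays were fixed before.

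Several values stood apart or differed between groups. Acta2 in SRFHKO day 8 replicate 3 had a log2 level of 10.125, against 9.979 to 9.982 in the other 3 arrays of its group. 2900093K20Rik in SRFHKO day 8 replicate 1 had a level of 4.547, against 4.984 to 5.066. These were 2 of 33 values tested in this group of 4 arrays, where chance gives about 1 in 20, or 1.65. Between the genotypes, the response to PE differed for Prkab2 (interaction 1.0723 on the log2 scale), Myh7 (-3.3431) and Sprr1a (3.4456). Among gene lists, camera called the same interaction for fatty acid oxidation (median -0.1252), cytosolic ribosomal proteins (-0.1564), extracellular matrix (0.428), cell cycle (0.4571), interferon response (-1.274), endothelial markers (0.2547) and lung markers (1.0647). With an estimated correlation 0 of these 7 lists passed, the smallest adjusted p being 0.790. No filter ended the calls of lung markers (median 0.79, adjusted p = 0.370), cell cycle genes (0.28, 0.309) and endothelial markers (0.25, 0.0516), and quantile normalisation those of fatty acid oxidation (-0.11, 0.0751) and cell cycle genes (0.47, 0.0751). No pseudocount ended the call of cell cycle genes (0.48, 0.0621) and a fit on the compared groups alone that of lung markers (adjusted p = 0.0624). Each of the 7 calls also ended without single arrays. The interferon median was -0.60 without control with PE replicate 3 (adjusted p = 0.116) and -0.69 without SRFHKO day 25 replicate 3 (0.252). Fatty acid oxidation lost its call without control day 25, control with PE or SRFHKO day 25 replicate 1, or SRFHKO with PE replicate 1 or 2 (adjusted p from 0.0751 to 0.217). The matrix list lost it without control day 25 replicate 1 (0.105) and ribosomal proteins without SRFHKO day 25 replicate 1 (0.0585). Cell cycle genes lost it without control day 25 replicate 1 or 2, control with PE replicate 1 or 3, SRFHKO day 25 replicate 1, or SRFHKO with PE replicate 2 or 3 (0.0646 to 0.264). Endothelial markers lost it without control day 25 replicate 1 or 2, control with PE replicate 1, SRFHKO day 25 replicate 1 or 3, or SRFHKO with PE replicate 3 (0.0589 to 0.192). Lung markers lost it without control day 25 replicate 3, control with PE replicate 2 or 3, SRFHKO day 25 replicate 1 or 3, or SRFHKO with PE replicate 1 or 2 (0.0522 to 0.140). Between the days, camera called a difference in the deletion effect for oxidative phosphorylation genes (-0.1787; adjusted p = 0.811 with an estimated correlation) and endothelial markers (-0.3301; adjusted p = 0.602 with an estimated correlation). The first call ended after quantile normalisation (adjusted p = 0.159), with brightness as a covariate (0.366) and without control day 8 replicate 2 (median -0.08, 0.703). Outside the tests by gene, 42 of 3504 probe sets with no gene symbol differed between SRFHKO and control hearts at day 25 without PE, 14 higher and 28 lower.

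For the contrasts of 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real split gave 295 genes for SRFHKO against control at day 25 without PE, where the highest of the others gave 0, and 206 with PE, where the highest of the others gave 0. For PE it gave 4 genes in control hearts and 37 in SRFHKO hearts, and the highest other split gave 2 in each case. Counting the real split, 1 of 10 splits gave as many genes in each of these contrasts. For gene lists the real split gave 6, 8, 7 and 10 calls in the same order, the highest other split gave 11, 12, 6 and 10, and 4, 4, 1 and 3 of the 10 splits gave as many. For the interaction of PE and genotype, 8 of 100 splits gave as many genes as the 3 of the real one and 32 gave as many lists as its 7, so chance cannot be excluded for either count. The highest other split gave 163 genes, which may point to a structure of the samples, and 12 lists. Its cause was not tested. The splits drawn could include a split that kept PE in 1 genotype and exchanged it in the other. Such a split would read the PE effect common to both genotypes, so it is no test of chance and could itself give a high count. Whether the 163 genes came from such a split was not checked.

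The Esr1 probe set was higher in every SRFHKO array than in any control array. Its levels were 8.19 ± 1.48 (SD, n = 10) against 3.26 ± 0.84 (SD, n = 8), the latter mean below the filter limit of 3.58, with a gap of 1.6775 between the lowest SRFHKO and the highest control array. As a hypothesis, this probe set may read the transcript of a tamoxifen-inducible Cre fused to estrogen receptor sequence. The gap prompted this hypothesis and cannot test it, so it stays open. Whatever this probe set reads, such a Cre carried by SRFHKO hearts alone would differ between SRFHKO and control hearts along with the Srf deletion. Their effects could then not be told apart in the genotype contrasts here. A rise of the mouse's own Esr1 transcript stays open too, because the other probe set above the filter differed by -0.158 but lay only 1.15 above the filter limit. Where either probe set lies relative to such a fusion is unknown here.

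Myh7 rose with PE in control hearts and not in SRFHKO hearts, where it was already high without PE. The tables argue against array brightness as the whole cause, since the interaction was -3.4149 ± 0.54 with brightness as a covariate (limma adjusted p = 0.0327). They also argue against a signal at the very top of the range. Taken over all 18 arrays, those of day 8 included, the highest Myh7 signal was 0.7906 of the highest on its array. Compression of signal below the top of the range was not tested. As a hypothesis, deletion alone may give the level that PE gives in control hearts: the difference of SRFHKO without PE from control with PE was -0.3129 ± 0.38 (adjusted p = 0.813), which does not show equal levels. Control hearts of day 8 lay 2.46 ± 0.43 above those of day 25 without PE (adjusted p = 0.00205), so the low group is control at day 25, and day and array run cannot be told apart there. The interaction itself missed the threshold without single arrays, with adjusted p up to 0.142 without control with PE replicate 1.

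Camera called interferon response genes higher with PE in control hearts (adjusted p = 0.794 with an estimated correlation) and lower in SRFHKO than control hearts with PE (adjusted p = 0.536 with an estimated correlation), with 0 of 23 members past limma's threshold over all genes in either (2 and 18 at an unadjusted p under 0.05). Without control with PE replicate 3 the first median went from 0.60 to -0.0545 (camera adjusted p = 0.972), so that call may come from that heart. The tables argue against fewer macrophages as the whole cause of the lower level in SRFHKO hearts with PE, since their markers had a median of -0.1167 (quartiles -0.47 to -0.01, 18 members) against -1.02 for the interferon list. Whether that heart also gave the lower level stays open. Without it the median was -0.6036 and the list kept its call at the preset correlation (camera adjusted p = 6.24e-05). However, the 2 other control hearts with PE lay at 0.86 and -0.63 in the mean deviation of the list, the second within the range of SRFHKO hearts with PE (-0.75 to -0.44).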

How the results depend on the processing

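Brightness as a covariate was chosen only after the result was seen, and leaving out arrays was not planned for the correlation of the deletion effects. The others were planned. For SRFHKO against control at day 8 the count of 8 genes was 16 over all probe sets, 5 with the mean of probe sets, 2 (0 of the 8 among them) with only the compared groups or only the compared days, 3 without an intensity trend and 2 to 51 with single arrays left out. At day 25 without PE the 295 were 489 over all probe sets, 40 with only the compared groups, 196 with only the compared days, 147 without a trend, 39 with brightness and 56 to 397 with arrays left out. For PE in control hearts the 4 were 2 after quantile normalisation, 1 with the mean of probe sets or without a trend, 10 with the compared groups (2 of the 4 among them), 7 with the compared days and 1 to 7 with arrays left out. For PE in SRFHKO hearts the 37 were 24 with the mean of probe sets or with brightness, 2 with the compared groups, 1 without a trend, 110 with array weights and 1 to 83 with arrays left out. At day 25 with PE the 206 were 130 with the compared groups, 73 without a trend, 56 with brightness and 47 to 205 with arrays left out. The interaction of PE and genotype, with 3 genes, gave 1 over all probe sets or with their mean, 0 without a trend and 0 to 7 with arrays left out. The interaction of day and genotype, with 0, gave 5 over all probe sets, 1 without a trend and 0 to 15 with arrays left out. Of the 51 list calls, 0 passed with an estimated correlation (17 list tests of 294 had an unadjusted p under 0.05) and fry called 14; counts were 36 after quantile normalisation and 46 to 59 with arrays left out. The correlation of the deletion effects of the 2 days, 0.0923, was 0.0439 with no filter and 0.0504 to 0.104 with arrays left out, lowest without control day 8 replicate 1. Under the alternatives run for named genes, 114 of 140 named calls missed the threshold at least 1 time, and 77 of 1085 uncalled values passed at least 1 time. Fits without a trend, among others, were not run for named genes. Kcnd3 at day 25 with PE, 0.76 in its brightest probe set, reversed to -0.406 with the mean of probe sets. The check for pairing by replicate number found none (20 pairs, correlations from -0.084 to 0.09, 0 over 0.1). Brightness before scaling, though, ran in the same order of replicates in all 4 groups of day 25. It was highest in replicate 2 and lowest in replicate 3, so shared processing by replicate number stays open. With the number as a replicate block the counts were 1, 300, 2, 37 and 217 in the order above, and 2 and 0 for the interactions. Lists had 54 calls with the block, and 45 of the 51 were kept. Leaving out arrays or groups leaves fewer samples for the spread; for the other settings the cause was not tested. Signal near the filter limit is the least precise.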

Other observations

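The heat shock genes below were chosen after their values were seen, and the lists were fixed before.

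Members of other fixed lists also moved at day 25. Among ion channel and conduction genes without PE, connexin 43 (Gja1, 0.74) and Kcnj11 (0.74, limma adjusted p = 0.0292), a subunit of the ATP-sensitive potassium channel, rose and Kcnip2 fell, 2 higher and 1 lower of 17 and the same counts when adjusted over the list alone. The median was -0.06, and camera, whose direction was up, made no call (adjusted p = 0.869). Among genes of glycolysis and glucose use, Pgam1 rose by 0.80 ± 0.13 (adjusted p = 0.00502), while muscle phosphofructokinase (Pfkm, -0.37 ± 0.09, 0.0320) and the pyruvate dehydrogenase kinase Pdk2 (-0.57 ± 0.11, 0.00999) fell. That is 1 higher and 2 lower of 26, or 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.214). Dusp1, a phosphatase of MAP kinases and an immediate early gene, rose with deletion by 0.62 ± 0.13 (adjusted p = 0.0212) and fell with PE in SRFHKO hearts by 0.77 ± 0.13 (0.0186). Both Dusp1 differences are measured from the same SRFHKO hearts of day 25 without PE, so they are not independent. Of 8 skeletal muscle markers, Myl1 rose while Ckm and Acta1 fell without PE (camera adjusted p = 0.735). With PE their median was 0.35 and their mean -0.13, with 2 lower over all genes (camera adjusted p = 0.830).

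The inducible heat shock gene Hspa1b lay at 5.57 ± 0.29 in control and 10.86 ± 1.30 in control hearts with PE, and at 6.56 ± 0.45 and 10.52 ± 3.40 in SRFHKO hearts (SD, n = 3 each). The differences with PE were 5.29 ± 1.02 in control (limma adjusted p = 0.0676) and 3.96 ± 1.02 in SRFHKO hearts (0.110), and neither passed. Hspa1a differed by 3.73 ± 0.95 (adjusted p = 0.203) and 3.19 ± 0.95 (0.168), and Hsph1 by 1.57 ± 0.43 (0.203) and 1.62 ± 0.43 (0.123). Hsp90aa1 rose with deletion at day 25 without PE by 1.09 ± 0.21 (limma adjusted p = 0.0106), as it did with PE in control hearts. Both rises are measured from the same control hearts of day 25 without PE, so they are not independent. For deletion, another probe set of the gene passed (1.14 ± 0.28, adjusted p = 0.0346 over all probe sets). A further probe set did not (0.72 ± 0.26, adjusted p = 0.149).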
